A study of Homo sapiens with 36 samples.

How the data were processed

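RNA was sequenced from 36 libraries of human umbilical vein endothelial cells (HUVEC), primary endothelial cells that line the vein of the umbilical cord. The labels assign 3 libraries, numbered as biological replicates, to each of 12 groups: 2 siRNAs in each of 6 culture conditions. One siRNA was non-targeting (NT) and the other was aimed at p27, the cyclin-dependent kinase inhibitor encoded by CDKN1B. According to the labels' protocols, cells were transfected for 24 h. They were then kept static for 48 h or exposed to 15 dyn/cm2 of shear stress for 72 h, in both cases in 2% FBS. Normal serum was 2% FBS and serum starvation was 0.2% FBS, each for 24 h. Low density was seeding at 50% confluency and high density was seeding at 1.5 times full density, each for 24 h in growth medium. The labels do not say whether replicates came from separate cultures or donors, so p-values measure the spread between these libraries, which may be technical. Flow and static also differed in duration, 72 h against 48 h, and that difference cannot be separated from shear.

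The deposited tables hold whole-number read counts per gene symbol, not normalized. The submitters' processing notes name FastQC, STAR, HTSeq and the hg38 build, without versions. The annotation release and the strand setting of the counting are not given in the sources used here, so reads of overlapping genes, of antisense partners and of near-identical copies such as ribosomal protein pseudogenes may be shared between them. The library kit named in the labels is an mRNA kit. Total counts per library ran from 11221916 to 21912367 over 33690 genes. Genes on the Y chromosome, XIST and TSIX (108 in all) were kept in library totals and left out of every table and test. Symbols matched GENCODE release 29 for 97.7% of the genes, and 258 of the 259 genes selected by the naming rule had 1 location there. Coordinates are those of GENCODE 29 on the same build.

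Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr, libraries were scaled by TMM (factors from 0.929 to 1.11), and 14223 genes were tested. A model with 1 mean per group was fitted to all 36 libraries with the robust quasi-likelihood method (glmQLFit), and contrasts were tested with glmQLFTest. The common biological coefficient of variation was 0.164. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. Every adjusted p of a gene below is from this edgeR test unless another tool is named. The 18 planned comparisons were flow against static, high against low density and starved against normal serum with each siRNA, the differences between the 3 NT responses, p27 siRNA against NT in each condition, and the change of each response with p27 siRNA. The mean effect of p27 siRNA over the 6 conditions, a contrast of the same model, was added after the data were examined. Levels are CPM of TMM-scaled libraries, given as mean ± SD, n = 3. With 3 libraries against 3, chance leaves 10% of genes without overlap between groups.

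Before the data were examined, 27 gene lists were fixed, as were the comparisons, the model, the rule for naming genes and the other settings to be tried. The lists were G1/S genes, G2/M genes, CDK inhibitors, cyclins with CDKs and pocket proteins, shear-responsive endothelial genes, Notch pathway, BMP and SMAD1/5 pathway, arterial, venous, tip cell, endothelial identity and junction, and endothelial inflammatory genes. The others were YAP/TAZ targets, p53 targets, immediate early and serum response genes, FOXO targets, cholesterol synthesis, glycolysis and hypoxia, ATF4 and unfolded protein response, TGF-beta and mesenchymal, interferon-stimulated, cytosolic ribosomal protein and mitochondrially encoded genes. Markers of other cells made up the last 4: smooth muscle, pericyte and fibroblast markers, leukocyte, epithelial and lymphatic endothelial markers. A gene may be on more than 1 list. Lists were tested against all other genes with camera (limma 3.58.1), adjusted over the lists of a comparison, with a preset correlation of 0.01 between members and again with the correlation estimated from the data. Counts of called members are given over all genes tested and, where stated, adjusted over the list alone.

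Named genes followed 1 rule. The 16 key genes were given in the 3 NT comparisons. Each list described contributed up to 3 called members with the largest change in the direction of most of its calls, at an average log2 CPM of at least 1. The 5 highest and 5 lowest called genes at an average log2 CPM of at least 2, with no overlap between groups, completed the NT comparisons, and the 3 highest and 3 lowest, without the overlap condition, were used elsewhere. Genes named outside the rule are said to be so. A fold against a group with 0 counts was computed from counts pooled over the 3 libraries of each group and their summed scaled sizes, against a floor of 3 counts, and is a lower bound. It can differ from a ratio of mean CPM. A ratio against 1 to 3 counts is given with its 95% exact counting interval. Intervals and floors cover counting error only, since the reads carry no molecular identifiers.

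Replicate pairs within groups were checked for duplicate libraries by a chi-square of their counts, which per degree of freedom was 6.96 to 77.4 over 36 pairs, far above sampling noise. Whether equal replicate numbers pair libraries was checked by correlating deviations from the group means. All 3 correlations exceeded 0.1 in 5 comparisons: p27 siRNA against NT under flow (0.372, 0.605, 0.15), in normal serum (0.224, 0.439, 0.225) and at high density (0.101, 0.496, 0.57), and with p27 siRNA high against low density (0.312, 0.612, 0.419) and starved against normal serum (0.165, 0.459, 0.201). The pairing there is read from the data, not from the labels.

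The other settings were RLE scaling, no low-count filter, a filter of CPM over 1 in at least 3 libraries, DESeq2 1.42.0, a fit of only the groups compared, the replicate number as a block, each library left out in turn, an absolute log2 fold change of at least 1, and no robust moderation. Fits without replicate 2 of every group, and of only the groups compared with a replicate block, were added after the data were examined. Where leaving out a library left fewer in a group, the pooled spread of the model was used.

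The steps were tested on simulated data made from the real means and library sizes. For NT flow against static (13875 genes), 25.8% of genes changed 1.5-fold, 66.2% of those changed 2-fold and 89.4% of those changed 4-fold were recovered, with 5 false calls of 124. For the change of the flow response with p27 siRNA (13874 genes), recovery was 9.52%, 56.1% and 86.4% at 1.5-fold, 2-fold and 4-fold, and at 4-fold it was 73.4% for the density response and 89.2% for the serum response (13869 genes each). For p27 siRNA against NT under flow (13885 genes), it was 26.9%, 78.1% and 84.4%, and for the mean of 6 conditions (13873 genes) 80.3%, 90.8% and 100%. A list of 30 members shifted 1.5-fold reached a camera p of 3.24e-56, and 7 of 200 random lists had p under 0.05 (13887 genes). The simulated genes were drawn independently of each other, so these lists do not test camera where members vary together between libraries. Words of 7 bases in the longest annotated 3' UTR of each gene were scored with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 for 10487 genes at an average log2 CPM above 2. The log2 fold change over its SE was regressed on 3' UTR length, GC content and average expression. A word's score was the mean residual of its genes, divided by the residual SD over the square root of their number. Average expression stayed in where length and GC content were left out. All 20 of 20 simulated words were recovered, each planted at the same fixed size among independent random scores. Without a planted word the lowest simulated score was -3.9, where the second lowest real word in static culture reached -5.5. The simulation was quieter than the data and does not test recovery of smaller shifts.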

Results

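The 36 HUVEC libraries fell into 12 groups of 3, from NT or p27 siRNA in static culture, under laminar flow, at low and high density, and in normal and low serum. Total counts per library ran from 11221916 to 21912367, and mitochondrial transcripts made up 3.1% to 4.51% of counts. The first principal component held 50% of the variance and the second 16.1%. MKI67, a marker of proliferating cells, stood at 374 ± 36 CPM in NT static and 236 ± 54 CPM in NT flow libraries, against 914 ± 162 to 1060 ± 308 CPM in the other 4 NT groups (mean ± SD, n = 3). One library, p27 flow replicate 3, had counts for 19630 genes where the others had 16607 to 17999. In the 8 density and serum groups, replicate 2 deviated from its group mean in the direction of the high density response more than the other replicates did, with correlations across genes of 0.14 to 0.67. Genes are not independent replicates, so these correlations describe libraries only.

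**Figure D1:**
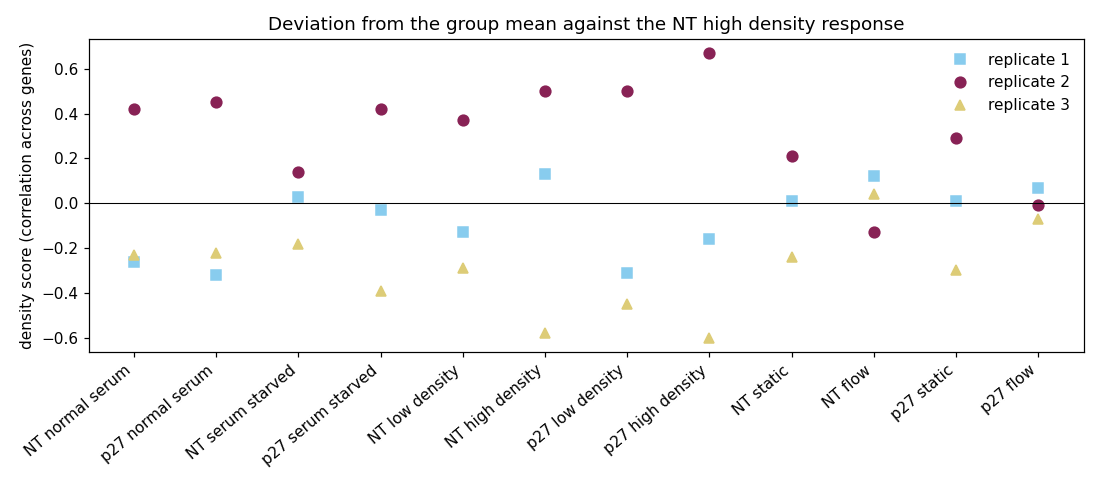
Each point is 1 library: the Pearson correlation across 14223 genes between its deviation from its group mean (log2 CPM) and the NT high density response, for the 12 groups on the horizontal axis and replicates 1 to 3 by symbol. Replicate 2 lies highest in all 8 density and serum groups (0.14 to 0.67) and in both static groups (0.21 and 0.29), and lies at -0.13 and -0.01 in the flow groups.

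CDKN1B, which encodes p27 (chromosome 12, 12715058 to 12722371), was lower with its siRNA in every condition. The 18 libraries with NT siRNA held 31.2 to 68 CPM and the 18 with p27 siRNA held 10.9 to 28.3 CPM, so no library contradicted its label. With p27 siRNA, CDKN1B stood at 40.3% of NT in static culture (20.9 ± 2.5 against 51.9 ± 4 CPM) and at 50.9% under flow (23.6 ± 4.1 against 46.3 ± 11 CPM). It stood at 35.5% at low density, 31.4% at high density, 27% in normal serum and 27.8% in low serum. The call passed in 5 conditions (adjusted p from 5.38e-06 to 0.00976) and missed under flow (log2 fold change -0.97, SE 0.21, adjusted p = 0.108). In static culture it ended without NT replicate 1 or 2 or p27 replicate 1 or 2 (log2 fold changes -1.25 to -1.28, adjusted p from 0.0637 to 0.125) and without replicate 2 of every group (-1.22, adjusted p = 0.0661), a fit added after the data were examined. With only the groups compared it ended in low serum, at low density and at high density (-1.84, -1.45 and -1.67, adjusted p = 0.0711, 0.0584 and 0.351).

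**Figure D2:**
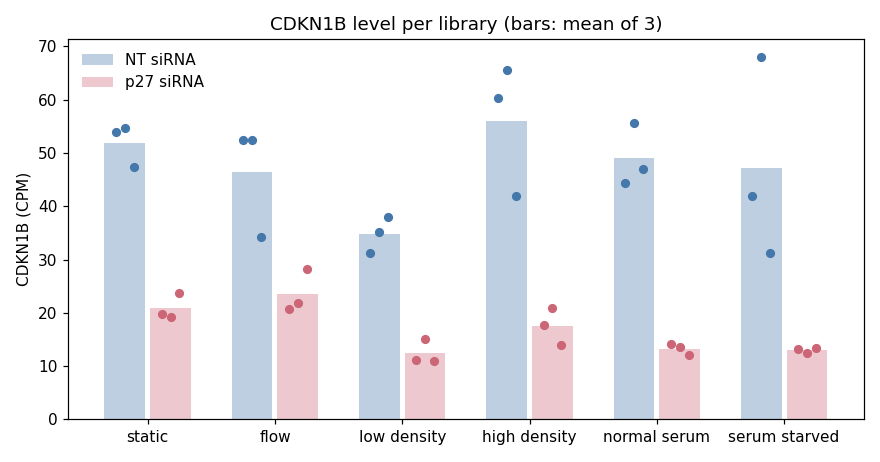
CDKN1B level in CPM (vertical axis) in each library (points) and its mean over 3 libraries (bars), for NT and p27 siRNA in 6 conditions. The p27 siRNA libraries span 10.9 to 28.3 CPM and lie below all NT siRNA libraries, which span 31.2 to 68 CPM.

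The first comparison asked how laminar flow changed cells with NT siRNA. KLF2 and KLF4, transcription factors induced by shear, rose from 12.1 ± 0.48 to 129 ± 14 CPM and from 3.57 ± 1.1 to 128 ± 19 CPM (log2 fold changes 3.42, SE 0.22, and 5.16, SE 0.31). NOS3, the endothelial nitric oxide synthase, rose by 1.39 (SE 0.19) and ID1, a BMP target, by 1.55 (SE 0.20). The proliferation genes MKI67 and CCNA2 fell by 0.66 (SE 0.19) and 0.80 (SE 0.22), and CTGF, a YAP/TAZ target, fell by 0.98 (SE 0.27). Of the CDK inhibitors, CDKN1A rose by 0.52 (SE 0.18) and CDKN2D rose from 2.16 ± 0.66 to 9.48 ± 1.3 CPM. CDKN1B had a log2 fold change of -0.16 (SE 0.20, adjusted p = 0.561), CDKN1C of -1.13 (SE 0.57, adjusted p = 0.119) and CCND1 of 0.00 (SE 0.28, adjusted p = 0.998). HES1 rose by 0.77 (SE 0.28) and HEY1, another Notch target, fell by 1.23 (SE 0.47). GJA4 (2.36, SE 0.99, adjusted p = 0.0643), ID3 (0.03, SE 0.23) and SMAD6 (0.17, SE 0.34) did not pass.

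Among the largest changes, CYP1B1, a cytochrome P450 enzyme, went from 2 counts over 3 static libraries to 12690 under flow, a ratio of 6300 with a 95% counting interval of 1740 to 52100. ADAMTSL2 was at least 446-fold higher, and NPNT had a ratio of 1570 (434 to 13000). PI16 rose by 10.17 (SE 0.61) and APLNR, the apelin receptor, by 9.94 (SE 0.52). SERPIND1 was at least 34.2-fold lower. AK5 fell by 6.44 (SE 0.49), LINC01235 by 5.72 (SE 0.43), CCBE1 by 5.63 (SE 0.58) and ETV4, an ETS factor downstream of growth factor signalling, by 5.47 (SE 0.41).

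By list, 16 of 23 shear-responsive genes rose and 2 fell (17 and 2 adjusted over the list alone, median 2.32, camera adjusted p = 1.15e-11). That call held with an adjusted p = 0.000714 with an estimated correlation. ELN rose by 7.24 (SE 0.97) beside CYP1B1 and PI16. Lymphatic endothelial markers fell in 6 of 9 members and rose in 2 (the same adjusted over the list alone, median -1.85, camera adjusted p = 0.0016, and adjusted p = 0.0147 with an estimated correlation). ANGPT2, a vessel-destabilising ligand that blood endothelium also makes, fell from 202 ± 54 to 6.54 ± 0.64 CPM, LYVE1, also on the venous list, from 72.2 ± 6.1 to 2.74 ± 0.19 CPM, and SEMA3A fell by 2.99 (SE 0.41).

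Of 54 G2/M genes 40 fell and 1 rose (42 and 1 adjusted over the list alone, median -0.69, camera adjusted p = 1.54e-09, but adjusted p = 0.743 with an estimated correlation), led by CENPE (-1.32, SE 0.22), PSRC1 (-1.30, SE 0.21) and CDC20 (-1.23, SE 0.21). Of 43 G1/S genes 7 fell and 1 rose (6 and 1 adjusted over the list alone, median -0.18, camera adjusted p = 0.0953), with CDCA7 at -1.77 (SE 0.22), MCM6 at -0.61 (SE 0.15) and UHRF1 at -0.60 (SE 0.24). Among 26 cyclins, CDKs and pocket proteins 3 rose and 5 fell (the same adjusted over the list alone, camera adjusted p = 0.578), including MYC (-2.09, SE 0.25), CCND2 (-1.39, SE 0.39) and CCNB1 (-1.23, SE 0.17). Among 7 CDK inhibitors 2 rose (2 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.764).

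Cholesterol synthesis genes rose in 13 of 25 (13 adjusted over the list alone, camera adjusted p = 0.00312, adjusted p = 0.743 with an estimated correlation), with LDLR, the low density lipoprotein receptor, at 1.39 (SE 0.20). LSS, the lanosterol synthase, and HMGCS1 stood at 1.17 (SE 0.28 and 0.44). Endothelial identity and junction genes rose in 13 of 28 and fell in 1 (14 and 1 adjusted over the list alone, camera adjusted p = 0.00129, adjusted p = 0.743 with an estimated correlation), led by JAM2 (2.72, SE 0.49), PTPRB (2.15, SE 0.19) and TEK, the angiopoietin receptor (1.83, SE 0.19). Interferon-stimulated genes fell in 14 of 27 and rose in 1 (15 and 3 adjusted over the list alone, camera adjusted p = 0.00123, adjusted p = 0.743 with an estimated correlation), with CXCL11 at -3.46 (SE 0.48), RSAD2 at -2.90 (SE 0.54) and IFI44L at -2.43 (SE 0.46). Inflammatory genes fell in 12 of 26 and rose in 1 (12 and 2 adjusted over the list alone, camera adjusted p = 0.0438, adjusted p = 0.743 with an estimated correlation). The chemokines CXCL8, CXCL1 and CXCL2 fell by 5.27 (SE 0.84), 2.86 (SE 0.56) and 1.67 (SE 0.49). Cytosolic ribosomal protein genes fell in 23 of 30 (26 adjusted over the list alone, median -0.52, camera adjusted p = 1.24e-05, adjusted p = 0.743 with an estimated correlation), with RPL8, RPS18 and RPS3 at -0.84, -0.78 and -0.75 (SE 0.18 to 0.19).

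Other lists held changes in both directions and did not pass camera in flow. Immediate early genes rose in 9 and fell in 11 of 26 (the same adjusted over the list alone, camera adjusted p = 0.112), with ETV4, EGR1 (-3.23, SE 0.41) and ETV5 (-2.81, SE 0.26) the lowest. Notch genes rose in 8 and fell in 4 of 20 (camera adjusted p = 0.225), with LFNG at 3.62 (SE 0.42), JAG1 at 2.52 (SE 0.46) and DLL1 at 1.90 (SE 0.41). BMP and SMAD1/5 genes rose in 9 and fell in 1 of 19 (camera adjusted p = 0.0953), led by BMPER (3.88, SE 0.95), ID2 (2.12, SE 0.29) and BMP2 (1.94, SE 0.35). For these 2 lists the counts adjusted over the list alone were the same. TGF-beta and mesenchymal genes rose in 10 and fell in 9 of 24, YAP/TAZ targets rose in 6 and fell in 8 of 23, and glycolysis and hypoxia genes rose in 4 and fell in 9 of 27 (10 and 10, 7 and 8, and 5 and 10 adjusted over the list alone, camera adjusted p = 0.874, 0.555 and 0.303). Arterial genes rose in 6 and fell in 7 of 22 (7 and 7 adjusted over the list alone, camera adjusted p = 0.874), and venous genes, with APLNR among them, rose in 6 and fell in 3 of 13 (7 and 3 adjusted over the list alone, camera adjusted p = 0.303). The medians of the arterial (-0.03), CDK inhibitor (-0.16) and TGF-beta (-0.16) lists lay below 0 where their means lay above it (0.58, 0.03 and 0.36). Camera pointed up for the arterial and CDK inhibitor lists and down for the TGF-beta list.

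Tip cell genes rose in 7 and fell in 3 of 22 (camera adjusted p = 0.303), with CD34 at 4.29 (SE 0.58) and NID2 at 4.15 (SE 0.25). The p53 targets rose in 3 and fell in 9 of 27 (camera adjusted p = 0.303), FOXO targets rose in 4 and fell in 5 of 23 (camera adjusted p = 0.874), and ATF4 and unfolded protein response genes rose in 3 and fell in 7 of 24 (camera adjusted p = 0.303). Adjusted over the list alone, the counts were 9 and 3 for tip cell genes, 3 and 9 for p53 targets, 5 and 5 for FOXO targets, and 4 and 8 for ATF4 genes. No mitochondrially encoded gene of 13 was called. Markers of other cells were measured beside these lists. Smooth muscle, pericyte and fibroblast markers rose in 2 and fell in 3 of 10 (median 0.65, mean -0.12, camera pointing up at an adjusted p = 0.921), and leukocyte markers rose in 1 of 3 (camera adjusted p = 0.654). Epithelial markers fell in 2 of 4 (camera adjusted p = 0.0424, adjusted p = 0.503 with an estimated correlation): the keratins KRT19, from 17.4 ± 3.7 to 3.38 ± 0.82 CPM, and KRT8, from 20.2 ± 2.5 to 9.07 ± 1.7 CPM. Adjusted over the list alone, the counts of these 3 marker lists were the same.

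In all, flow changed 5346 of 14223 genes with NT siRNA (2727 higher, 2619 lower), of which 2167 changed at least 2-fold. Leaving out any 1 of the 6 libraries gave 4237 to 5042. Flow lasted 72 h and static culture 48 h, so the comparison holds both differences.

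**Figure D3:**
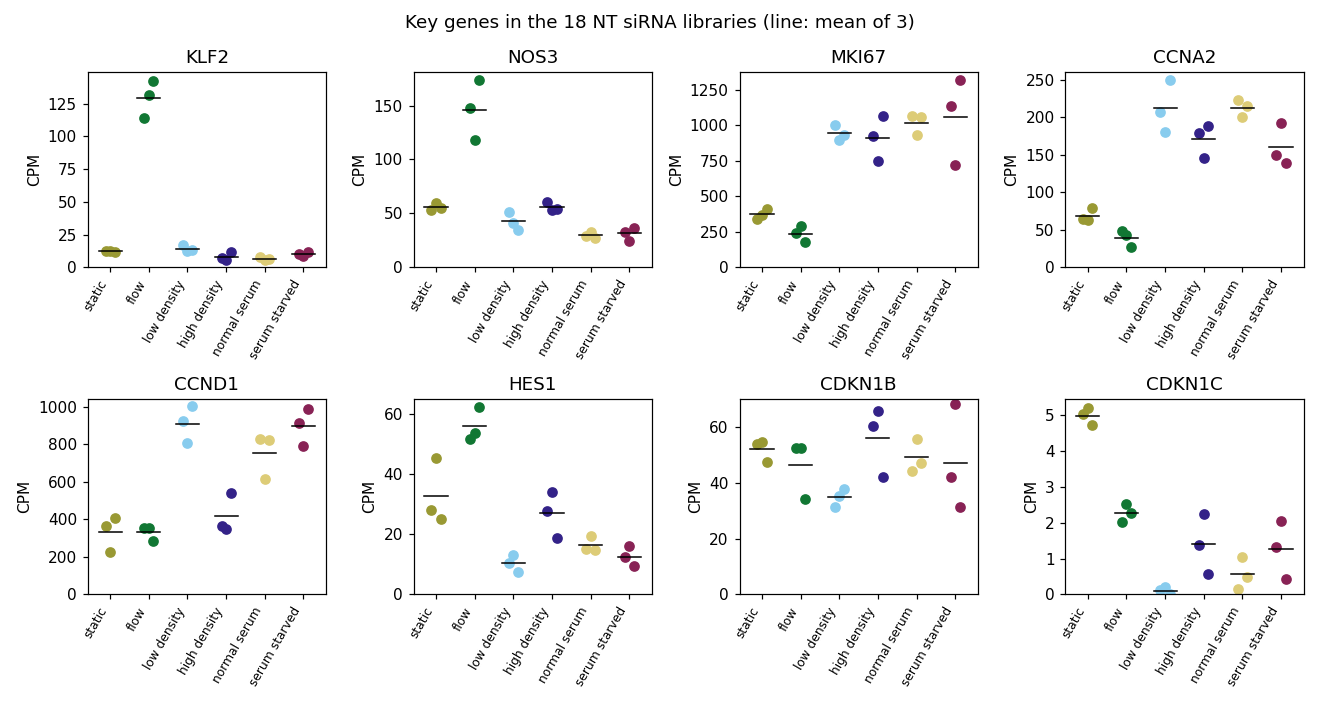
CPM of 8 key genes (vertical axes, linear, each from 0) in the 18 NT siRNA libraries (points) by condition, with lines at the mean of 3. KLF2 lies at 129 ± 14 CPM under flow against 12.1 ± 0.48 CPM in static culture, and MKI67 is lower in static and flow libraries than in the others.

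The density comparison asked what crowding changed in cells with NT siRNA. CDKN1B rose from 34.7 ± 3.4 CPM at low density to 55.9 ± 12 CPM at high density (log2 fold change 0.69, SE 0.21, adjusted p = 0.0248), with the 3 high density libraries above the 3 low density ones. CDKN1C, encoding p57, rose from 0.11 ± 0.11 to 1.4 ± 0.83 CPM (3.64, SE 0.96), and CCND1, cyclin D1 (chromosome 11, 69641087 to 69654474), fell by 1.12 (SE 0.28). The Notch targets HES1 and HEY1 rose by 1.38 (SE 0.30) and 1.88 (SE 0.48), while KLF2 and KLF4 fell by 0.81 (SE 0.22) and 1.06 (SE 0.34). MKI67 (-0.05, SE 0.19), CCNA2 (-0.31, SE 0.22), CDKN1A (-0.07, SE 0.18), CTGF (-0.54, SE 0.27), NOS3 (0.40, SE 0.19), GJA4 (4.81, SE 1.69), ID1 (0.00, SE 0.19), ID3 (0.35, SE 0.23) and SMAD6 (0.94, SE 0.35) did not pass (adjusted p from 0.0532 to 1).

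Among genes at an average log2 CPM of at least 2 with no overlap between groups, the largest increases were of AQP1, the water channel (4.74, SE 1.48), IL33 (4.46, SE 1.31), PDK4 (3.56, SE 0.88) and BMF (3.56, SE 1.01). APLNR had 1 count over the low density libraries and 33 at high density, a ratio of 30.8 (95% counting interval 5.16 to 1250). G0S2 fell by 2.33 (SE 0.51), TMEM158 by 2.19 (SE 0.54), FST, the activin antagonist follistatin, by 2.02 (SE 0.43), CDCP1 by 1.95 (SE 0.52) and MYEOV by 1.93 (SE 0.48).

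G1/S genes fell in 16 of 43 (25 adjusted over the list alone, median -0.43, camera adjusted p = 5.48e-11, adjusted p = 0.305 with an estimated correlation), with TIPIN at -0.82 (SE 0.17), GINS2 at -0.80 (SE 0.21) and the recombinase gene RAD51 at -0.69 (SE 0.20). G2/M genes fell in 5 of 54 (3 adjusted over the list alone, median -0.30, camera adjusted p = 4.93e-05, adjusted p = 0.475 with an estimated correlation), among them CKS2, CDC20 and TUBB4B (-0.72, -0.66 and -0.58, SE 0.20 to 0.21). CDK inhibitors rose in 3 of 7 (3 adjusted over the list alone, camera adjusted p = 0.0276, adjusted p = 0.297 with an estimated correlation), the other being CDKN2B (0.94, SE 0.22). Cyclins, CDKs and pocket proteins rose in 1 and fell in 3 of 26 (the same adjusted over the list alone, camera adjusted p = 0.00302, adjusted p = 0.305 with an estimated correlation), with RBL1 at -0.53 (SE 0.18) and CDK2 at -0.37 (SE 0.09) beside CCND1.

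FOXO targets rose in 10 and fell in 1 of 23 (13 and 1 adjusted over the list alone, median 0.69, camera adjusted p = 4.93e-05, adjusted p = 0.297 with an estimated correlation), with PDK4, SESN3 (2.78, SE 0.75) and PIK3IP1 (2.59, SE 0.55). Venous genes rose in 7 of 13 and arterial genes rose in 7 and fell in 1 of 22 (8, and 12 and 1, adjusted over the list alone, camera adjusted p = 0.000167 for each, adjusted p = 0.297 with an estimated correlation for each). SEMA3G rose by 2.99 (SE 0.94), the Notch ligand DLL4 by 2.02 (SE 0.55) and the lymphatic growth factor receptor FLT4 by 1.44 (SE 0.36). Notch genes rose in 5 of 20 (9 adjusted over the list alone, camera adjusted p = 0.00119, adjusted p = 0.297 with an estimated correlation). BMP and SMAD1/5 genes rose in 4 of 19 (6 adjusted over the list alone, camera adjusted p = 0.00197, adjusted p = 0.297 with an estimated correlation), with SMAD7 at 1.26 (SE 0.33). Endothelial identity and junction genes rose in 9 and fell in 1 of 28 (14 and 1 adjusted over the list alone, camera adjusted p = 4.93e-05, adjusted p = 0.297 with an estimated correlation), led by JUP (1.76, SE 0.43) and MMRN1 (1.08, SE 0.23). Interferon-stimulated genes rose in 8 and fell in 1 of 27 (15 and 1 adjusted over the list alone, camera adjusted p = 4.13e-05, adjusted p = 0.305 with an estimated correlation), with RSAD2 at 1.71 (SE 0.51), IFIT2 at 1.39 (SE 0.36) and IFIH1 at 1.08 (SE 0.19).

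YAP/TAZ targets fell in 5 and rose in 1 of 23 (the same adjusted over the list alone, camera adjusted p = 0.00197, adjusted p = 0.305 with an estimated correlation), with ANKRD1 at -1.54 (SE 0.33), FJX1 at -1.04 (SE 0.23) and CYR61 at -0.71 (SE 0.19). Immediate early genes fell in 6 of 26 (7 adjusted over the list alone, camera adjusted p = 0.0365, adjusted p = 0.305 with an estimated correlation), including DUSP1 (-1.23, SE 0.24). Glycolysis and hypoxia genes fell in 8 and rose in 1 of 27 (11 and 1 adjusted over the list alone, camera adjusted p = 0.0245, adjusted p = 0.35 with an estimated correlation), with HK2, LDHA and PFKFB3 at -0.87 (SE 0.29), -0.68 (SE 0.19) and -0.66 (SE 0.19). The p53 targets rose in 6 and fell in 1 of 27 (9 and 2 adjusted over the list alone, camera adjusted p = 0.0093, adjusted p = 0.305 with an estimated correlation), with TP53INP1 at 1.66 (SE 0.34). Ribosomal protein genes had a median of -0.26 with 1 of 30 fallen, RPLP1 (none adjusted over the list alone, camera adjusted p = 0.000423, adjusted p = 0.524 with an estimated correlation). Of the markers of other cells, LYVE1 (2.05, SE 0.66), PROX1 (1.97, SE 0.32) and FLT4 made 3 of 9 lymphatic markers that rose (3 adjusted over the list alone, camera adjusted p = 0.106). The lymphatic median of 0.58 became 0 with a member at 0 counts set to its bound. LCP1 fell by 1.78 (SE 0.50) among 3 leukocyte markers (1 adjusted over the list alone, camera adjusted p = 0.155). Of 10 smooth muscle, pericyte and fibroblast markers edgeR called none in the main fit, while DESeq2 and a replicate block in edgeR each called 2 higher. The list passed camera (median 1.85, adjusted p = 0.0154, and adjusted p = 0.305 with an estimated correlation).

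Replicate 2 stood apart in many of the genes named for density. In each of the 8 density and serum groups it held the highest level of 3 for AQP1, GJA4, IL33, BMF, SEMA3G, PDK4, SESN3, PIK3IP1, CDKN1C, LYVE1, TP53INP1, HEY1 and MMRN1 (mean log2 differences from the other 2 replicates 2.87, 2.47, 2.31, 2.06, 1.9, 1.77, 1.48, 1.08, 1.44, 1.44, 0.73, 0.62 and 0.3). It held the lowest for TMEM158, HK2, CCND1, RBL1 and RAD51 (-1, -0.7, -0.47, -0.36 and -0.35). PDK4, SESN3 and PIK3IP1 are the 3 members named of the FOXO list. Without replicate 2 of every group, 4 of 27 interferon-stimulated genes rose where 8 had, and 8 of 20 Notch genes where 5 had. Glycolysis and YAP/TAZ members that rose became 3 and 2, ribosomal ones that fell became 3, and the single FOXO and arterial members that fell were lost. No other list count given above moved by over 1.5 times in that fit. CDK inhibitors that rose became 2 of 7 where 3 had, and which members these were was not followed.

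High density changed 2193 genes (1053 higher, 1140 lower), of which 451 rose and 104 fell at least 2-fold. The count moved with single libraries left out. It was 360 without low density replicate 1, 216 without low density replicate 3, 541 without high density replicate 1 and 99 without high density replicate 2. It was 2659 without high density replicate 3 and 3451 in a fit of only the 6 libraries compared.

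The serum comparison asked what 0.2% against 2% FBS changed in cells with NT siRNA. NID2, a basement membrane protein, rose from 43.3 ± 12 to 139 ± 27 CPM (1.69, SE 0.23), and the growth factor genes PGF and PDGFB rose by 1.39 (SE 0.23) and 1.18 (SE 0.22). These 3 were among 4 of 22 tip cell genes that rose (12 adjusted over the list alone, median 0.46, camera adjusted p = 9.34e-10), a call that held with an adjusted p = 0.00217 with an estimated correlation. Of 25 cholesterol synthesis genes 6 rose (15 adjusted over the list alone, median 0.69, camera adjusted p = 2.91e-10, adjusted p = 0.465 with an estimated correlation), with MVD at 1.36 (SE 0.36), LSS at 1.33 (SE 0.28) and LDLR at 0.76 (SE 0.20). Inflammatory genes rose in 3 of 26 (10 adjusted over the list alone, camera adjusted p = 0.0004, adjusted p = 0.525 with an estimated correlation): TRAF1 (1.67, SE 0.31), RELB (1.57, SE 0.27) and NFKB2 (0.91, SE 0.14), the last 2 subunits of NF-kB. BMP and SMAD1/5 genes fell in 3 and rose in 1 of 19 (the same adjusted over the list alone, camera adjusted p = 0.0226, adjusted p = 0.525 with an estimated correlation), with SMAD9 at -1.23 (SE 0.21), ID2 at -1.20 (SE 0.30) and ID1 at -0.85 (SE 0.20).

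In the fit of all libraries edgeR called no member of the 4 cell cycle lists in low serum, and DESeq2 called 1 CDK inhibitor higher. Without replicate 2 of every group 8 of 43 G1/S genes, 8 of 54 G2/M genes and 4 of 26 cyclins, CDKs and pocket proteins fell and 1 of 7 CDK inhibitors rose. Other lists moved in that fit too: 14 of 22 tip cell genes, 12 of 25 cholesterol genes, 5 of 26 inflammatory genes, 9 of 28 endothelial identity genes, 7 of 20 Notch genes, 6 of 22 arterial genes, 6 of 27 p53 targets, 6 of 24 ATF4 genes and 5 of 23 FOXO targets rose, and 5 of 19 BMP genes and 5 of 13 mitochondrially encoded genes fell. With all libraries the 43 G1/S genes had a median of -0.21 (camera adjusted p = 1.26e-05, adjusted p = 0.636 with an estimated correlation), and the 54 G2/M genes had a median of -0.14 (camera adjusted p = 0.00122, adjusted p = 0.785 with an estimated correlation). Adjusted over the list alone, 1 CDK inhibitor of 7 passed and no member of the other 3 lists did. No key gene other than ID1 passed: CDKN1B was at -0.06 (SE 0.20), CDKN1A at 0.55 (SE 0.18), CDKN1C at 1.15 (SE 0.69), CCND1 at 0.25 (SE 0.28), CCNA2 at -0.41 (SE 0.22), MKI67 at 0.06 (SE 0.19), KLF2 at 0.68 (SE 0.22) and KLF4 at 0.01 (SE 0.35). NOS3 (0.08, SE 0.19), HES1 (-0.38, SE 0.29), HEY1 (0.07, SE 0.48), GJA4 (0.18, SE 1.14), ID3 (0.05, SE 0.23), SMAD6 (-0.75, SE 0.35) and CTGF (-0.23, SE 0.26) also missed (adjusted p from 0.0904 to 0.994 over the 15). At an average log2 CPM of at least 2, with no overlap between groups, the highest were CHRNA1 (2.51, SE 0.63), PCDH12 (2.06, SE 0.45), PRDM1 (1.97, SE 0.48), CHST1 (1.70, SE 0.28) and NID2. The lowest were BDNF (-2.14, SE 0.50), MGARP (-2.00, SE 0.35), RFLNA (-1.72, SE 0.40), SNAPC1 (-1.47, SE 0.29) and SMAD9.

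Low serum changed 217 genes (175 higher, 42 lower). Of these, 80.6% were higher, against 64.3% of 658 with DESeq2. That share did not hold without serum starved replicate 2 (756 higher and 874 lower, 46.4% higher) or without replicate 2 of every group (1314 higher and 1446 lower, 47.6% higher). The count moved with every library left out, to 38, 79 and 21 without normal serum replicates 1, 2 and 3 and to 16, 1630 and 80 without serum starved replicates 1, 2 and 3, and it was 607 in a fit of only the 6 libraries compared. Serum starved replicate 2 held MKI67 at 721 CPM where the other starved replicates held 1140 and 1320 CPM, but CCNA2 at 192 CPM where they held 150 and 139 CPM, and the mean log2 CPM of the G2/M list was 6.87 to 6.92 over the 3 libraries.

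**Figure D4:**
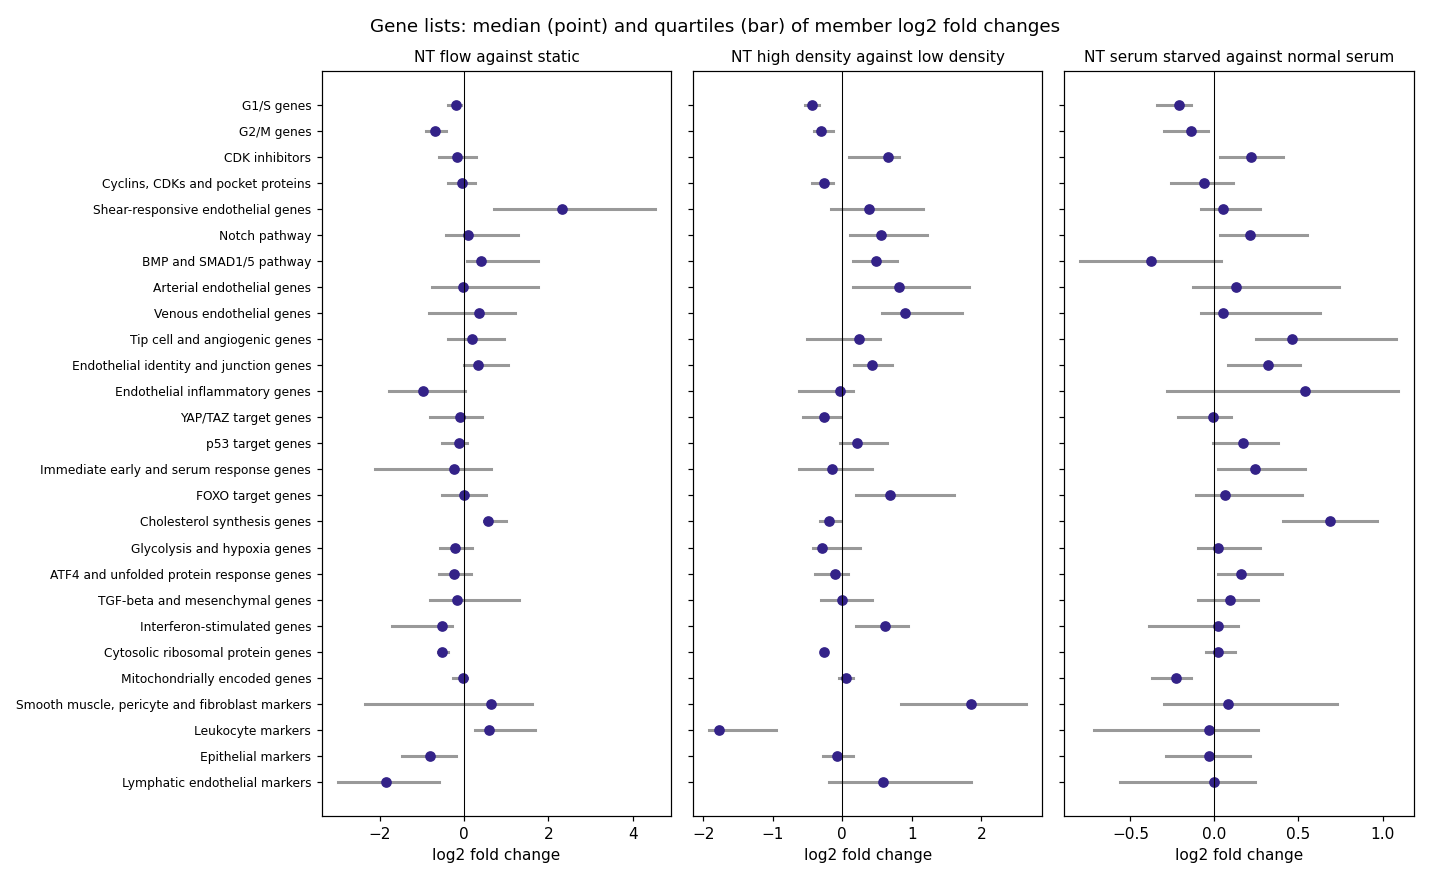
Median (point) and quartiles (bar) of member log2 fold changes for the 27 gene lists (vertical axis) in the 3 NT comparisons. Each panel has its own horizontal scale. The shear-responsive list has its median at 2.32 with flow, 0.38 with density and 0.05 in low serum, and the G1/S list lies at -0.18, -0.43 and -0.21.

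The 3 responses were then set against each other. Flow and density shared 212 genes higher and 254 lower, where independent lists would share 202 and 210, and their log2 fold changes had r = 0.02 across 14223 genes. Flow and low serum shared 80 higher and 20 lower (33.6 and 7.73 if independent, r = 0.11), and density and low serum 24 and 6 (13 and 3.37 if independent, r = 0.24). These pairs share no libraries. All 3 responses had 9 genes higher and 1 lower (2.48 and 0.62 if independent). NID2, the protocadherins PCDH12 and PCDH1, MEF2D, AHDC1, RNF122, WASF2, KIAA1671 and the sterol transporter ABCG1 rose in each, and SNAPC1 fell by 1.40, 1.33 and 1.47. Of these 10, PCDH1, MEF2D, AHDC1, RNF122, WASF2, ABCG1 and KIAA1671 were named after their values were seen. The number shared was 38 with DESeq2 and 73 with only the groups compared.

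By direct test, 4178 genes responded differently to flow and density (2099 higher and 2079 lower in flow minus density). The controls of the 3 responses were unlike: static culture lasted 48 h in 2% FBS, low density 24 h in growth medium and normal serum 24 h in 2% FBS. Their MKI67 levels with NT siRNA were 374 ± 36, 946 ± 53 and 1020 ± 73 CPM. Differences between responses can therefore reflect controls, medium or duration, and were not assigned to the stimuli alone. Genes ranked from here on had an average log2 CPM of at least 2. PI16 (9.41, SE 2.18), CMKLR1 (8.92, SE 1.96) and MCF2L (8.52, SE 2.47) were highest and SERPIND1, FILIP1 (-7.31, SE 1.03) and LYVE1 (-6.76, SE 0.98) lowest. Shear-responsive genes (12 of 23 higher, 4 lower, and 13 and 5 adjusted over the list alone) and lymphatic markers (6 of 9 lower, also adjusted over the list alone) differed by camera with an estimated correlation too (adjusted p = 0.00842 and 0.00143 with an estimated correlation). Flow and low serum differed in 3236 genes (1593 higher, 1643 lower), highest in CYP1B1, PI16 and APLNR and lowest in SERPIND1, AK5 and ETV4. Density and low serum differed in 137 genes (71 higher, 66 lower), with SLC40A1, ART4 and PROX1 highest and CDCP1, MYEOV and MAMDC2 lowest. Cholesterol genes had a median difference of -0.95 there with no member called (13 lower adjusted over the list alone, camera adjusted p = 1.5e-09, adjusted p = 0.303 with an estimated correlation). The 137 became 441 with DESeq2 and 670 with only the groups compared. Leaving out starved replicates 1, 2 and 3 gave 15, 633 and 24, normal serum replicates 2 and 3 gave 27 and 33, low density replicates 1, 2 and 3 gave 17, 70 and 72, and high density replicates 1 and 2 gave 12 and 20.

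The last comparisons asked what p27 siRNA changed. In the fit of all libraries few genes besides CDKN1B passed within a condition. MLLT11 fell beside CDKN1B in static culture (-1.13, SE 0.20), normal serum (-1.83, SE 0.20), low serum (-1.69, SE 0.20), low density (-1.93, SE 0.21) and high density (-1.92, SE 0.21). TMEM64 fell in normal serum (-1.34, SE 0.26), ATL3 in low serum (-0.99, SE 0.15), ZNF32 at low density (-1.10, SE 0.21) and SUMF1 at high density (-0.93, SE 0.18). HYAL1, a hyaluronidase, rose in normal serum (1.33, SE 0.27), low serum (1.33, SE 0.25) and at low density (1.26, SE 0.26), LIMS2 in normal serum (1.24, SE 0.21) and at low density (1.35, SE 0.22), H1F0 in normal and low serum (0.71, SE 0.14 in each), UNC13D at low density (1.59, SE 0.33) and ITGA6, an integrin, at high density (0.57, SE 0.11). The counts were 2 in static culture (both lower), 17 in normal serum (3 higher, 14 lower), 11 in low serum (3 higher, 8 lower), 23 at low density (7 higher, 16 lower) and 11 at high density (2 higher, 9 lower). Replicate numbers paired the libraries in normal serum and at high density, where a replicate block in a fit of only the 6 libraries compared, added after the data were examined, gave 35 genes (10 higher, 25 lower) and 367 (123 higher, 244 lower). That fit without the block gave 2 and 1. In conditions that did not meet the rule for pairing, the block gave 144 in static culture, 669 at low density and 0 in low serum.

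Under flow edgeR called 0 genes with p27 siRNA, at an unadjusted p under 0.05 in 1643, and DESeq2 called 51. There the replicate numbers paired the libraries, and a replicate block gave 20 in the fit of all libraries and 25 in a fit of only those compared. Leaving out NT flow replicate 2 gave 422 and leaving out p27 flow replicate 1 gave 391, while leaving out p27 flow replicate 3 gave 0. Leaving out single libraries gave 0 or 1 gene in static culture (all but p27 replicate 3), 4 to 9 in normal serum (all but p27 replicate 1), 3 to 13 at low density (all but p27 replicate 1), 4 to 7 in low serum and 2 to 6 at high density (all 6 libraries). DESeq2 called 15 in static culture (46.7% higher, against 0 of 2), 33 in normal serum, 18 in low serum, 94 at low density and 35 at high density.

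Over the mean of the 6 conditions, a contrast added after the data were examined, 648 genes passed (292 higher, 356 lower), 43 of them at least 2-fold. MLLT11 (-1.58, SE 0.08), CDKN1B (-1.53, SE 0.09) and the chemokine receptor ACKR3 (-1.34, SE 0.25) were lowest, and PI16 (1.60, SE 0.40), COL1A2 (1.32, SE 0.27) and ITGB4 (1.25, SE 0.26) highest among genes at an average log2 CPM of at least 2. The cell cycle lists held few calls: BRIP1 rose among 43 G1/S genes (0.28, SE 0.08), HMGB2 among 54 G2/M genes (0.22, SE 0.06), and CDKN1A fell with CDKN1B among the CDK inhibitors (-0.26, SE 0.07). Adjusted over the list alone the counts were 1, 0 and 2. The p53 targets CDKN1A and TIGAR (-0.24, SE 0.05) fell among 27 (4 adjusted over the list alone, camera adjusted p = 0.000418, adjusted p = 0.216 with an estimated correlation). KLF2 rose by 0.35 (SE 0.09) and NOTCH4 by 0.44 (SE 0.10). Markers of other cells moved with the siRNA too, COL1A2 among smooth muscle, pericyte and fibroblast markers and LCP1 (0.97, SE 0.21) among leukocyte markers.

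Flow with p27 siRNA changed 5561 genes (2640 higher, 2921 lower), and 4255 of the 5346 called with NT siRNA were called the same way. The log2 fold changes of the flow responses had r = 0.91 across genes. Shear-responsive genes rose in 15 and fell in 2 of 23 (16 and 2 adjusted over the list alone, adjusted p = 0.00464 with an estimated correlation), G2/M genes fell in 44 and rose in 1 of 54 (46 and 1 adjusted over the list alone, adjusted p = 0.715 with an estimated correlation) and G1/S genes fell in 17 of 43 (17 adjusted over the list alone, adjusted p = 0.87 with an estimated correlation). By pooled counts NPNT was at least 1480-fold and ADAMTSL2 at least 588-fold higher, APLNR rose by 11.02 (SE 0.57), SERPIND1 was at least 29.1-fold lower, TLL1 fell by 7.16 (SE 0.54) and FSTL5 had 3 counts under flow against 262. Leaving out p27 flow replicate 3 gave 4839 genes.

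High density with p27 siRNA changed 2258 genes (1219 higher, 1039 lower), 1115 of them called the same way with NT siRNA (r = 0.71). IL33 (3.96, SE 1.23), GUCY1A1 (3.79, SE 1.27) and PDK4 (3.68, SE 0.89) were highest and G0S2 (-2.44, SE 0.52), TMEM158 (-2.11, SE 0.54) and RFLNA (-1.77, SE 0.39) lowest. Interferon-stimulated genes rose in 14 of 27 (16 rose and 1 fell adjusted over the list alone, camera adjusted p = 3.05e-07, adjusted p = 0.438 with an estimated correlation) and G1/S genes fell in 2 of 43, SLBP and RFC2 (none adjusted over the list alone, camera adjusted p = 0.00467, adjusted p = 0.626 with an estimated correlation). The count was 0 with only the groups compared and 4388 in that fit with a replicate block, and leaving out low density replicates 1, 2 and 3 gave 995, 3814 and 119 and high density replicate 2 gave 50. Low serum with p27 siRNA changed 50 genes (41 higher, 9 lower), 41 of them as with NT siRNA (r = 0.57), among them NID2 (1.73, SE 0.23), MAMDC2 (2.00, SE 0.33), FAM89A (1.70, SE 0.37), BDNF (-2.20, SE 0.51), MGARP (-1.99, SE 0.35) and RFLNA (-1.87, SE 0.40). That count was 225 with a replicate block, 144 with DESeq2, and 2 with only the groups compared, which became 881 with a block. Leaving out normal serum replicates 1, 2 and 3 gave 6, 275 and 1, and starved replicates 1 and 2 gave 12 and 1.

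The change of each response with p27 siRNA was tested as an interaction. No gene passed in edgeR or in DESeq2 for flow, density or serum, with 394, 380 and 117 genes at an unadjusted p under 0.05 in edgeR. Leaving out p27 flow replicate 1 gave 2 genes for flow. With 3 libraries per group, simulated interactions were recovered in 9.52%, 7.58% and 9.38% of genes at 1.5-fold and 56.1%, 32.3% and 45.5% at 2-fold for flow, density and serum, so changes of that size in the response were not excluded. With p27 siRNA, CDKN1B stood at 50.9% of NT under flow and 40.3% in static culture, against 27% to 35.5% in the other conditions. The knockdown was partial and differed between conditions, so the responses under a fuller loss of p27 were not tested.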

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

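All tests of explanations in this part were chosen after the results they measure had been seen. The results below are gene lists whose response differed between p27 and NT siRNA by camera with the preset correlation, in flow, density or serum. None of these differences passed with an estimated correlation (adjusted p from 0.202 to 0.976 with an estimated correlation). No single gene's response differed in edgeR or in DESeq2 (394, 380 and 117 genes at an unadjusted p under 0.05 in edgeR for flow, density and serum). Exact two-sided permutation of the siRNA labels of the list means, 400 relabellings each, gave p = 0.04 as its lowest value over the 27 lists and 3 responses, for leukocyte markers with flow, and 0.995 after Benjamini-Hochberg adjustment over these 81 tests. These relabellings ignored replicate numbers, which paired the libraries under flow, in normal serum and at high density. Exchange within equal numbers was run for the G1/S list with density alone.

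At high density G1/S genes fell less with p27 siRNA than with NT siRNA, with a median difference of log2 fold changes of 0.27 over 43 genes (camera adjusted p = 9.7e-08, adjusted p = 0.946 with an estimated correlation). The exact permutation gave p = 0.305 for this list, and exchange of siRNA labels only between equally numbered libraries gave p = 0.0938 (64 relabellings), so genes of the list that vary together between libraries could give the difference with no effect of the siRNA. A single library did not carry it, since the median difference stayed between 0.16 and 0.43 with each of the 12 libraries left out, and it was 0.30 without replicate 2 of every group. An effect of p27 loss on the density response stays open and was not shown here.

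The other differences, as medians of the p27 response minus the NT response, were these. With flow, shear-responsive genes differed by -0.42, cholesterol synthesis genes by -0.19, TGF-beta and mesenchymal genes by -0.28, interferon-stimulated genes by -0.26 and ribosomal protein genes by -0.17. Marker lists differed with flow as well: smooth muscle, pericyte and fibroblast markers by -0.99, leukocyte markers by -1.51 over 3 genes and epithelial markers by -0.55 over 4. With density G2/M genes differed by 0.20, and with low serum ribosomal protein genes by -0.11.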

How the results depend on the processing

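The fits without replicate 2 of every group, and of only the groups compared with a replicate block, as well as the mean over 6 conditions, were chosen after seeing the data. No named gene called in either fit changed sign with the 6 settings listed next or with single libraries left out. Values called in neither did: 30 with single libraries left out, 2 each with DESeq2, RLE scaling and the block, and 1 each without a low-count filter and with only the groups compared. Of the named genes only CDKN1B was followed in the added fits, and only for p27 siRNA against NT, not for its rise at high density. Of 566 named gene values, the number whose call was lost was 0 with CPM over 1 in at least 3 libraries, 1 with DESeq2, 2 with RLE scaling, 0 with the replicate block, 96 without a low-count filter and 110 with only the groups compared, where 562 could be computed. Leaving out single libraries lost the call of 1002 of 5004 values. Over all these settings together, 42 of 1080 values lost their call for NT flow, 232 of 910 for NT density and 88 of 516 for NT serum. The 162 list results include those with no camera call to lose, and 47 lost their camera call with an estimated correlation. Of the calls described for the 3 NT responses, only shear-responsive and lymphatic lists with flow and tip cell genes in low serum held in that test. With only the groups compared 3 of 157 lost their call and with the block 1, and 6 and 7 gained one in these 2 fits. RLE scaling and the robust setting moved no count by over 1.5 times. Without replicate 2 of every group, the called members rising or falling moved by over 1.5 times in 11 of 27 lists for NT density (8 counts up, 4 down) and 24 of 27 for NT serum (31 up), and with the replicate block in 10 and 13 (10 and 14 counts up). No median of a list of 81 compared changed sign by 0.1 or more with RLE or DESeq2.

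Counts that moved by over 1.5 times follow, and the cause was not tested except where a size threshold or fewer libraries give it by construction. With an absolute log2 fold change of at least 1, the counts were 2167 for NT flow, 555 for NT density, 68 for NT serum, 2215 for flow minus density, 1736 for flow minus serum, 6, 4, 8 and 3 for p27 siRNA in normal serum, low serum, low density and high density, 2327, 515 and 23 for flow, density and serum with p27 siRNA, and 43 for the mean of 6 conditions. With no low-count filter p27 siRNA gave 7 in static culture, 4 under flow and 18 at high density. With DESeq2 the counts were 658 for NT serum, 441 for density minus serum, 15, 51, 33, 18, 94 and 35 for p27 siRNA in static culture, flow, normal serum, low serum, low density and high density, 144 for serum with p27 siRNA and 38 for the genes shared by the 3 responses. With only the groups compared they were 3451 for NT density, 607 for NT serum, 670 for density minus serum, 1, 2, 0, 1 and 1 for p27 siRNA in static culture, normal serum, low serum, low density and high density, 0 and 2 for density and serum with p27 siRNA, and 73 shared.

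A replicate block gave 720 for NT serum, 559 for density minus serum, 6 and 20 for p27 siRNA in static culture and flow, 225 for serum with p27 siRNA and 110 shared, and it moved no other count by over 1.5 times. In the 7 comparisons that did not meet the rule for pairing, the labels give only a number, and 1 or 2 of 3 numbers correlated best with their own (numbers 1, 2 and 3 at -0.02, 0.23 and 0.271 for NT density and 0.03, 0.296 and 0.213 for NT serum), so equal numbers may share more than a number in part of the libraries. A block in a fit of only the groups compared gave 4721 for NT density, 1702 for NT serum, 1412 for density minus serum, 144, 25, 35, 0, 669 and 367 for p27 siRNA in static culture, flow, normal serum, low serum, low density and high density, 4388 and 881 for density and serum with p27 siRNA, and 234 shared. Without replicate 2 of every group the counts were 2760 for NT serum, 44, 3, 6, 9 and 5 for p27 siRNA under flow, in normal serum, low serum, low density and high density, 358 for serum with p27 siRNA, 428 for the mean of 6 conditions and 271 shared.

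Leaving out 1 library at a time gave 4237 to 5042 for NT flow, 99 to 2659 for NT density, 16 to 1630 for NT serum, 3349 to 4304 for flow minus density, 2529 to 3554 for flow minus serum and 12 to 633 for density minus serum. For p27 siRNA against NT it gave 0 to 2 in static culture, 0 to 422 under flow, 4 to 12 in normal serum, 4 to 7 in low serum, 3 to 24 at low density and 2 to 6 at high density. With p27 siRNA it gave 4419 to 5428 for flow, 50 to 3814 for density, 1 to 275 for serum, 0 to 2 for the change of the flow response, 0 for the changes of the density and serum responses, and 501 to 813 for the mean of 6 conditions. At 11221916 to 21912367 counts per library, genes with few counts in a group carry ratios with wide counting intervals, as for CYP1B1 (1740 to 52100).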

Other observations

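The tests of the first 2 patterns below were chosen after their results had been seen, as were the splits of p27 against NT libraries and of the mean of 6 conditions and the sorting of splits by the labels they kept or the pairs they parted. The other splits were planned. Genes that recurred between conditions were picked out after their values were seen. Across the 6 comparisons of p27 with NT siRNA, 34 genes passed at least once and 10 at least 3 times, of which 8 were lower. Beside CDKN1B and MLLT11, each called in 5 conditions, ATL3 (mean of 6 conditions -0.73, SE 0.06), CCNY (-0.46, SE 0.04) and SERINC3 (-0.53, SE 0.04) were called in 4. AKAP11 (-0.45, SE 0.05), SCARB2, a lysosomal membrane protein (-0.53, SE 0.05), and SUMF1 (-0.84, SE 0.07) were called in 3. HYAL1 (1.06, SE 0.10) and the linker histone gene H1F0 (0.56, SE 0.06) were the 2 higher ones.

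Some of the genes lower with p27 siRNA shared a sequence in their 3' UTRs. The 7-base word GAGTTCT, of 16166 words the one whose genes were lowest with p27 siRNA in static culture (score -8.7), was also lowest in 4 of the other 5 conditions (-9.4 to -13.7) and ranked 1544 under flow (-2.7). Of 279 genes lower over the 5 conditions other than static, 42.3% carried it, against a median of 13.6% and a highest value of 19.7% in 1000 sets matched on 3' UTR length. Of 139 higher genes 10.8% did (14.4% in matched sets). The shift per gene was small: over these 5 conditions the median log2 fold change was -0.03 for all genes with the word and -0.01 for those without. Among the lower genes it was -0.30 and -0.25. 3' UTR length or base composition was argued against as the whole cause, because the word was in the lowest 1% in 4 of 5 conditions with both in the regression, in which it had also been picked. The scores depended on that: without length and GC content they were -2.8 in static culture (rank 3130), 7.2 under flow (9180), -19.7 in normal serum (332), -11.7 in low serum (1), -9.7 at low density (3) and -3.2 at high density (4). A candidate explanation is a seed match of the siRNA, whose sequence is not given in the sources used here. Of the 279 lower genes 161 lacked the word, which also lies in 2 of 2 CDKN1B mRNAs. The recurrently lower genes MLLT11, ATL3, CCNY, SERINC3, AKAP11, SCARB2 and SUMF1 each carried 1 to 3 copies, where 12.7% of the 10487 genes scored had the word. FAM174B, called lower in 2 conditions, carried none. Static culture, where the word was picked, is among the conditions these calls came from. Only this exact word in the longest annotated 3' UTR was followed, so its absence does not set the share that a seed match could account for. Loss of p27 itself stays open too, and it was not tested apart, since the labels name a single p27 siRNA treatment and no rescue.

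Replicate 2 of the density and serum groups lay toward high density. Its score, the correlation of its deviation with the NT density response, was the highest of 3 in 8 of 8 groups, and its mean deviation had r = 0.72 with that response across genes, 0.39 with the serum response and 0.05 with the flow response. The pattern was not limited to these groups: replicate 2 also scored highest in NT static (0.21) and p27 static (0.29), though not in NT flow (-0.13) or p27 flow (-0.01). AQP1 was highest in replicate 2 in 8 of 8 groups (mean difference 2.87, SD 0.78 over groups) and HMOX1 lowest in 8 of 8 (-1.26, SD 0.48), both chosen after their values were seen. Depth was argued against as the whole cause by 3 groups in which replicate 2 lay between the others in total count and still scored highest. In p27 high density, among these 3, replicate 2 held 13980662 counts and replicate 3 held 13889358. Replicate 2 was the shallowest in 4 groups and the deepest in 1. GC content or gene length was argued against by a correlation of 0.71 after both were regressed out. Cultures further along the density response at harvest and other differences of replicate 2 cannot be told apart. Replicate 2 scored highest in 4 of the 4 serum groups, which did not set the response (r = 0.52), but those groups are part of the pattern, and the labels give no culture density at harvest.

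Other splits of the libraries were fitted with the same model. Splits of 3 against 3 libraries number 10, too few for a share under 0.05. There the real split was the only 1 of the 10 with as many genes for NT flow (5346, highest other 0), NT density (2193, 0), NT serum (217, 1), flow with p27 siRNA (5561, 16) and serum with p27 siRNA (50, 3). For p27 against NT the same held in normal serum (17, 1), low serum (11, 0), low density (23, 0) and high density (11, 2). In static culture 3 splits of 10 gave at least 2 genes (highest other 22). Under flow the real count in edgeR was 0 (1643 at an unadjusted p under 0.05, 51 with DESeq2). Any split reaches 0, so the 10 of 10 that did test nothing. There NT replicates 1 and 3 with p27 replicate 1 against the others gave 1301. For density with p27 siRNA 2 of 10 splits gave as many as the real 2258, and low density replicates 1 and 3 with high density replicate 3 against the others gave 2722. Those 2 splits point to a structure of the libraries besides their groups: each keeps 2 of the 3 equally numbered pairs together. They were not refitted with a replicate block. For the real splits of these 2 comparisons the block gave 20 and 3065 genes. In the 5 comparisons whose numbers paired the libraries, the other 3 splits that part all 3 pairs, as the real one does, gave 0 genes each, and the highest other split parted 1 pair.

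Of 100 splits drawn for each of the others, the real one included, 1 gave as many genes for flow minus density (4178, highest other 3319) and 3 for flow minus serum (3236, 3641). Neither share tests the difference: splits that kept the labels of neither response gave 0 genes, and the 10 that kept the flow labels alone gave 2475 to 3319 and 2621 to 3641, of which 0 and 2 reached the real count. For density minus serum 5 of 100 did (137, 1523). That share does not test the difference either, for the reason given next, so chance stays open. The other splits with as many genes in these 3 tests each kept the labels of 1 response (flow for 3641, serum for 1523), and the 77 that kept neither gave at most 1 gene for density minus serum. For the mean effect of p27 siRNA over 6 conditions 1 of 100 did (648, 362), a share under 0.05. This contrast and its splits were chosen after the data were seen, and the splits were not sorted by the pairs they parted. For the genes shared by the 3 responses 1 of 100 did (10, 0), but this test was void, since other splits of NT flow or NT density called 0 genes and so could share none. The interactions called 0 genes in edgeR and in DESeq2 (394, 380 and 117 at an unadjusted p under 0.05 in edgeR). Any split reaches a count of 0, so the 100 of 100 that did test nothing. The highest others were 920 for flow, 1087 for density and 85 for serum. The 920, 1087 and 85 came from splits that kept the siRNA labels of neither condition, and splits that called many genes where the real one called 0 point to a structure of the libraries. For density the 1087 became 1 with a replicate block, and the split with 1021 became 0, so these counts followed the replicate numbers. For flow and serum the 920 and 85 became 1359 and 269, which a shared number for all groups did not account for, and their cause stays open. The 12 other splits that parted all 6 equally numbered pairs, as the real one does, gave 0 genes for flow and for density and at most 85 for serum.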
